A study of Mus musculus with 6 samples.

How the data were processed

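Gene expression was measured in heart ventricles of 6 male mice, each on its own Affymetrix array. All 6 mice lacked dystrophin and carried a single utrophin allele (the "Het" genotype on the C57BL/10 background, per the labels). In the finerenone group 3 mice ate chow with 100 ppm of the drug from 4 weeks of age, and the 3 untreated mice ate the same chow without it; all were 20 weeks old at collection. The labels call the mice biological replicates and say that they were assigned to the groups at random. RNA integrity numbers were above 7.3 in all samples, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

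The deposited values are log2 summaries per probe set made by the authors with RMA in Affymetrix Expression Console and Transcriptome Analysis Console, per the submitters' processing notes. RMA corrects background, normalizes the arrays to a common distribution and summarises the probes of a set. Program versions, the annotation build and any further transformation of the signal are not given in the sources used here. The table held 72688 probe sets, of which 65956 were transcript clusters and 6732 were controls. Values ran from 1.94 to 19.93, and the highest lay at the log2 of 1000000, so transcripts close to that level, such as Ankrd1, had little room to rise. The median over transcript clusters ran from 4.43 to 4.48 across the 6 arrays, and positive control probe sets exceeded negative ones with an area under the curve of 0.822 to 0.849. The number of arrays, 3 per group, limits the precision of every difference.

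Transcript clusters were named through the platform annotation, with symbols updated by Entrez identifier to the RefSeq genes of mouse assembly GRCm38.p6. A single symbol was listed for 30604 clusters, several for 2146 and none for 33206, and clusters of the last 2 kinds were not named. This left 30063 genes. For the 429 genes with several clusters, the one with the highest mean over the 6 arrays was used. No filter on dim genes was applied.

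Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over all 30063 genes with a threshold of 0.05. Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists with at least 5 measured genes. There were 36 lists, 20 of pathways and 16 of cell type markers. Of their 608 genes, 546 were measured, 17 lay in clusters with several symbols and 45 were not named here; 2 lists, of erythroid and of male-linked genes, had under 5 measured genes and were not tested. Members were also counted at an adjusted p below 0.05 over all genes and adjusted over the list alone. Per-array list means were compared by an exact permutation test, which with 3 arrays against 3 cannot give a p below 0.1. Fold changes are finerenone minus untreated on the log2 scale, with the standard error of the limma fit. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 handled the tables and plots.

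The tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took up to 10 genes per direction with the largest difference among those past the threshold whose groups did not overlap. Since no gene passed, the places were filled with the largest differences at an unadjusted p below 0.01, with groups that did not overlap and a mean in the higher group at or above the median of all genes. That median was 4.94, below the median of the negative control probe sets in every array (5.04 to 5.33). The rule therefore let signals near background through. Symbols of predicted genes, olfactory receptors, microRNAs, small nucleolar RNAs and immune receptor segments were skipped by pattern, and Scarna17, a small Cajal body RNA, matched none of these patterns. A fixed set of 20 genes of the corticosteroid receptors, their targets, the dystrophin complex, cardiac stress and fibrosis was always named, except 2 that are not reported here. For each list, members with the smallest unadjusted p were named, 4 for a list past the threshold and at most 2 for another. A first look at the values with the fits planned beforehand preceded the final calculation. The examination of hepatocyte and clock genes, of gene span, and of the share of higher genes was chosen after that look, as were the clock score as a covariate and the removal of a trend with gene span and signal level.

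Alternatives were quantile normalization, median centring and cyclic loess of the deposited values, filters on dim genes (17708 genes at or above the median signal, 11346 at a mean of at least 6), the mean of a gene's clusters, a trended robust prior, array weights, the replicate number as a block, each array left out in turn, all 65956 clusters, other thresholds, and camera with an estimated correlation, camera on ranks and fry. Camera with an estimated correlation, camera on ranks and fry used only the fit of all 6 arrays without a covariate. They therefore do not test a call that a list gained in another fit. Simulated arrays had the spread of the real genes and 30063 genes, with 50 genes changed per size, all drawn from genes at a mean of at least 6. The limma fit called 14% of the genes changed by 0.5 on the log2 scale and 64% of those changed by 1. It called 90% of those changed by 2 and 96% of those changed by 4, with 2 false calls. All 200 genes were changed at once, and the large changes ease the adjusted threshold for the small ones. These shares therefore do not carry over to dim genes or to fewer changes. Camera called 100% of simulated lists of 12 independent genes shifted by 0.35 and 4% of unshifted ones; real lists hold correlated genes, which that simulation left out.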

Results

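Ventricular transcripts of 3 finerenone-treated and 3 untreated mice were compared to ask which genes differed in hearts of dystrophic mice fed this non-steroidal antagonist of the mineralocorticoid receptor. Each value is a log2 signal of 1 array per mouse. The 6 arrays correlated between 0.989 and 0.994 over transcript clusters.

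The 10 named genes with higher signal in treated hearts were led by Ccl12 and Tbca. Ccl12, a chemokine that attracts monocytes, averaged 7.15 ± 0.14 in treated and 5.92 ± 0.54 in untreated hearts (SD, n = 3 each), a log2 difference of 1.23 (2.34-fold). Alox5ap, the protein that activates 5-lipoxygenase for leukotriene synthesis, averaged 10.09 ± 0.06 against 8.94 ± 0.26, a difference of 1.15. Il33, an alarmin cytokine, differed by 0.99 ± 0.25 (SE), Slc25a33, a mitochondrial pyrimidine nucleotide carrier, by 1.02 ± 0.25, and Tbca, a tubulin-folding cofactor, by 1.20 ± 0.30. Lrrc52, Mrps36-ps2, Cmbl, Psmg4 and Acyp2 differed by 0.87 to 1.18. Without untreated replicate 1, which stood apart from the other arrays, the 10 differences ran from 0.615 (Acyp2) to 1.09 (Lrrc52). Ccl12 was then at 0.99, Tbca at 0.93 and Mrps36-ps2 at 0.79. None of these genes passed the adjusted threshold in limma, where the smallest adjusted p was 0.597.

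In the other direction, signal was lower in treated hearts for Nr1d1, the clock repressor Rev-erb alpha, with 10.13 ± 0.05 against 10.82 ± 0.21 (SD, n = 3 each) and a log2 difference of -0.68. Vldlr, a lipoprotein receptor, differed by -0.64 ± 0.17 (SE), Nr0b2, the nuclear repressor Shp, by -0.64 ± 0.15, and Spaar, a small polypeptide of lysosomes, by -0.74 ± 0.14. Pde3a, a phosphodiesterase of cardiac muscle, and Grk5, a kinase of G protein-coupled receptors, each differed by -0.50. Scarna17, Akap12, Pglyrp1 and Cmya5 differed by -0.76 to -0.52. Pglyrp1 (4.84 against 5.37) and Spaar (5.18 against 5.92) lay near the median of the negative controls, 5.04 to 5.33 across arrays. These 10 genes did not pass either (adjusted p = 0.597 in limma).

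**Figure D1:**
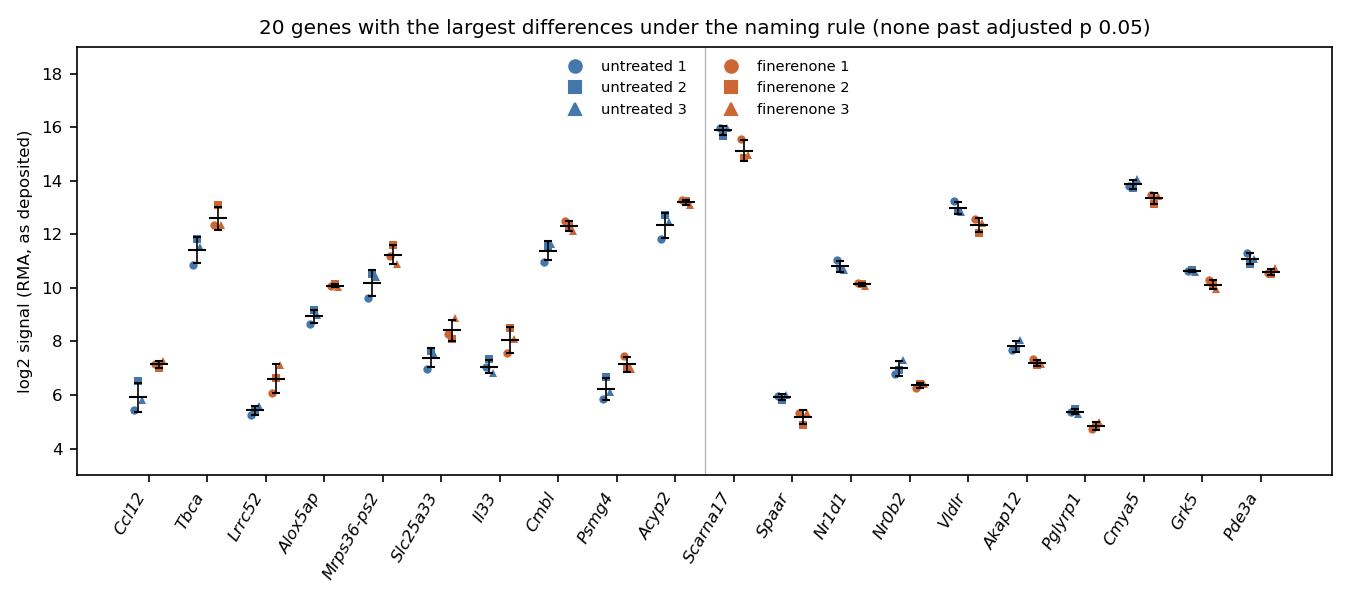
Log2 signal (vertical axis, RMA values as deposited) of the 20 genes named by rule, with 1 point per array, and bars for the mean and SD of 3 arrays per group. The 10 genes on the left had higher and the 10 on the right lower signal in all 3 treated arrays, as the rule required, and none had an adjusted p below 0.05.

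Over all 30063 genes, limma found 0 past the adjusted threshold, and over all 65956 transcript clusters also 0. At an unadjusted p below 0.05 there were 2347 genes, 1711 higher and 636 lower, where 1503 are expected by chance. With a fold of at least 1.5 there were 495 such genes, and with a fold of at least 2 there were 23. Of the 2347 genes 72.9% were higher, a share that was 59.2% after quantile normalization, 65.2% after cyclic loess and 68.7% after median centring. It was 47.5% of 1836 genes with the span and level trend removed, an alternative chosen after the data were seen. That removal centres the differences (median over all genes 0.001), so a near-even share was largely built in and does not test the direction. The groups did not overlap for 3712 genes (12.3%, against 10% by chance).

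Neither corticosteroid receptor passed the threshold. Nr3c2, the mineralocorticoid receptor that finerenone blocks, had a log2 difference of -0.11 ± 0.07 (SE) and Nr3c1, the glucocorticoid receptor, one of 0.03 ± 0.10. Of the genes that both receptors regulate, Sgk1, a kinase that acts on sodium channels, differed by -0.56 ± 0.27, Tsc22d3 (Gilz) by 0.27 ± 0.15, Per1 by -0.16 ± 0.16, Fkbp5 by 0.10 ± 0.31, Zbtb16 by 0.29 ± 0.52 and Lcn2 by 0.51 ± 0.47. Among 17 measured corticosteroid target genes 10 were higher and 7 lower, with a median of 0.05, a mean of -0.11 and a camera test that pointed down (adjusted p = 0.319). The list passed in camera with the clock score as a covariate, an alternative chosen after the data were seen (median -0.20, adjusted p = 0.0390). Camera with an estimated correlation, run without that covariate, gave an adjusted p = 0.675. The median of the list was -0.08 without finerenone replicate 3, -0.04 without untreated replicate 1 and close to 0 with array weights. The widest difference in that list was in Cdkn1a, the cell cycle inhibitor p21, at -1.66 ± 0.50, with 12.13, 10.24 and 10.27 in the treated arrays against 12.42 to 12.69 in the untreated ones. Errfi1, an inhibitor of the EGF receptor, differed by -0.73 ± 0.25, and by -0.45 without finerenone replicate 2. Without untreated replicate 1, which stood apart from the other arrays, the difference in Sgk1 was -0.26, and that in Tsc22d3 was 0.12 without untreated replicate 3. Signs for Nr3c1, Fkbp5, Zbtb16, Per1 and Lcn2 depended on the setting or on single arrays. In this list 0 members passed over all genes and 0 adjusted over the list alone. The renin-angiotensin-aldosterone list (13 genes) had a median of 0.02, a mean of 0.00 and a test that pointed down (adjusted p = 0.644).

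For the genes of the disease model, Dmd differed by -0.22 ± 0.32 (SE) and Utrn by -0.32 ± 0.10 (adjusted p = 0.597 in limma). Dmd ran from -0.57 to -0.04 with single arrays left out. Since all mice shared the genotype, neither gene checks the labels. The sarcoglycan Sgca differed by 0.55 ± 0.15, and the dystrophin-associated list (16 genes, 7 higher and 9 lower) had a median of -0.03 (adjusted p = 0.302), which was -0.12 without finerenone replicate 3 (adjusted p = 0.0519) and 0.00 without finerenone replicate 2 or untreated replicate 2. Of the cardiac stress genes, Nppa (0.45 ± 0.40), Nppb (-0.82 ± 0.79) and the beta myosin heavy chain Myh7 (-0.60 ± 0.50) varied widely within the groups. Nppa measured up to 19.60 (finerenone replicate 2), close to the highest value of 19.93, so it had little room to rise. With single arrays left out, Nppa ran from 0.04 to 0.73, Nppb from -1.55 to -0.08 and Myh7 from -0.95 to -0.08, and Nppb turned to 0.46 with the clock covariate. That list of 14 genes had a median of 0.03, a mean of 0.08 and a test that pointed down (adjusted p = 0.992). Of the matrix genes, Col1a1 differed by 0.04 ± 0.24, Col3a1 by -0.13 ± 0.34, Postn by 0.57 ± 0.32, Tgfb1 by -0.29 ± 0.13 and Ccn2 by -0.36 ± 0.23. Thbs4, a thrombospondin, differed by 0.58 ± 0.17. The fibrosis list of 31 genes had 22 higher and 9 lower members and a median of 0.04 (adjusted p = 0.779). Without finerenone replicate 2 it passed with a median of 0.14 (adjusted p = 0.0447), but it had an adjusted p = 0.973 with an estimated correlation. With single arrays left out the signs for Col1a1 and Col3a1 turned, Postn ran from 0.25 to 0.91 and Ccn2 from -0.62 to -0.18, and Tgfb1 was -0.16 without finerenone replicate 3.

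Of the 34 lists tested, 3 passed in camera at the preset correlation, all of cell type markers. All 11 endothelial genes were lower in treated hearts, with a median log2 difference of -0.35 (camera adjusted p = 8.36e-05). Among them Kdr, the VEGF receptor 2, differed by -0.86 ± 0.27 (SE), Cdh5 (VE-cadherin) by -0.73 ± 0.31, Ptprb by -0.48 ± 0.19 and Tie1 by -0.43 ± 0.21. All 15 macrophage and monocyte genes were higher, with a median of 0.31 (adjusted p = 0.00259), among them Lyz2 (lysozyme) by 0.75 ± 0.31, Fcgr1 by 0.60 ± 0.20, Ccr2 by 0.51 ± 0.14 and Itgam by 0.32 ± 0.15. Ccr2 was dim, with 5.75 in treated and 5.24 in untreated hearts, near the median of the negative controls. Of 12 smooth muscle and pericyte genes 11 were lower, with a median of -0.15 (adjusted p = 0.00533), Pdgfrb by -0.55 ± 0.16, Myh11 by -0.49 ± 0.32, Tagln by -0.44 ± 0.26 and Notch3 by -0.19 ± 0.11. Each of the 3 lists had an adjusted p = 0.662 with an estimated correlation, so no call held there. In none of them did a member pass over all genes or adjusted over the list alone. With that setting 0 of the 34 lists had even an unadjusted camera p below 0.05. The T and NK list, with an estimated correlation of -0.077, went from an unadjusted camera p of 0.00952 to one of 0.0537. A lost call therefore does not show that correlated genes had made it. The simulation did not check that setting. Other divisions of the same 6 arrays shifted up to 12 lists at the preset correlation, and in all 34 lists leaving out some single array moved the median by over 1.5 times or turned its sign.

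Per array, the mean of the endothelial list was 10.99 ± 0.15 in treated and 11.41 ± 0.32 in untreated hearts (SD, n = 3 each; exact permutation p = 0.2). The macrophage list averaged 8.52 ± 0.16 and 8.21 ± 0.21 (exact permutation p = 0.2), and the smooth muscle list 8.59 ± 0.10 and 8.79 ± 0.18 (exact permutation p = 0.2). Arrays of the groups overlapped in all 3 lists. They did not overlap for the oxidant defence, T and NK cell, and Schwann cell and nerve lists, none of which passed in camera. Each of those had an exact permutation p = 0.1, the lowest that this test can give, and 10% of lists would separate so by chance. Without untreated replicate 1, Cdh5 was at -0.45, Tie1 at -0.21 and Myh11 at -0.20. Without that array the smooth muscle list also lost its call (median -0.10, camera adjusted p = 0.173) and the endothelial median was -0.21 (adjusted p = 0.0209), while without untreated replicate 2 the smooth muscle and endothelial medians were -0.25 and -0.53. Without finerenone replicate 1 the smooth muscle median was -0.09, Tagln was at -0.29 and Lyz2 at 0.48, without finerenone replicate 3 Tagln was at -0.71 and Itgam at 0.18, and without untreated replicate 3 Notch3 was at -0.12. The macrophage list lost its call among genes at a mean of at least 6 (adjusted p = 0.0712), and its median was 0.17 without finerenone replicate 1, 0.21 without finerenone replicate 3 and 0.17 without untreated replicate 3.

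**Figure D2:**
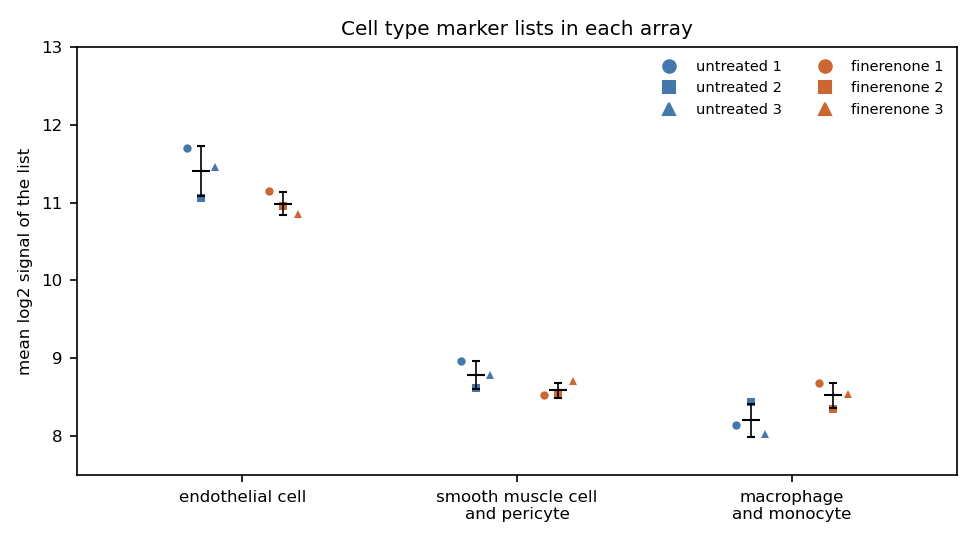
Mean log2 signal (vertical axis) of the 3 cell type marker lists that passed in camera at the preset correlation, with 1 point per array and bars for the mean and SD of 3 arrays per group. The groups overlap in each list, as for the endothelial markers, where untreated replicate 2 (11.07) lies below finerenone replicate 1 (11.15).

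Immune and inflammatory genes gave list shifts that did not pass in the planned test. The interferon list had 18 of 24 members higher and a median of 0.11 (adjusted p = 0.0581), with Bst2 (tetherin) at 0.81 ± 0.23 (SE) and Ifit1 at 0.47 ± 0.12. It passed in camera after quantile normalization (adjusted p = 0.0300), after cyclic loess (0.0273), with array weights (0.0460), without finerenone replicate 3 (0.0116), with the clock covariate (0.0141) and with the span and level trend removed (0.0498), but not with an estimated correlation (adjusted p = 0.675). Its median ran from 0.06 to 0.21 with single arrays left out. In the cytokine list 17 of 27 were higher with a median of 0.10 (adjusted p = 0.925), Ccl6 by 0.75 ± 0.30. MHC class II genes had a median of 0.04, a mean of 0.05 and a test that pointed down (adjusted p = 0.944). Markers of T and NK cells (median -0.09, adjusted p = 0.0581), B cells (-0.12, 0.0581) and granulocytes and mast cells (-0.08, 0.160) were mostly lower and mostly dim. The T and NK list passed with array weights (0.0460), without finerenone replicate 2 (0.0447) and with the clock covariate (0.0390), the B cell list on ranks (0.0337) and without finerenone replicate 1 (0.0273), finerenone replicate 2 (0.0447) or untreated replicate 3 (0.0396), and the granulocyte list without finerenone replicate 2 (0.0447). Each of these 3 lists had an adjusted p = 0.662 with an estimated correlation. Oxidant defence genes had a median of 0.18 (adjusted p = 0.122), with Ncf1, a subunit of the phagocyte oxidase, at 0.50 ± 0.15 and Hmox1 at 0.46 ± 0.16. That list passed without finerenone replicate 2 (0.0447) and with the clock covariate (0.0390), but had an adjusted p = 0.662 with an estimated correlation.

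Metabolic lists did not pass in the planned test either. Oxidative phosphorylation had 26 of 35 genes higher and a median of 0.15 (adjusted p = 0.0527), with Cox5b at 0.42 ± 0.13 (SE) and Ndufb5 at 0.53 ± 0.17. Its median was 0.03 after quantile normalization (adjusted p = 0.998) and 0.04 without untreated replicate 1 (0.897), and the list did not pass after cyclic loess (0.403) or with an estimated correlation (0.868). It passed with the trended prior (0.0360), on ranks (0.0239), with the clock covariate (0.0377) and without finerenone replicate 2 (0.0115), untreated replicate 2 (0.00136) or untreated replicate 3 (0.00435). Glucose uptake and glycolysis had 13 of 16 higher and a median of 0.10 (adjusted p = 0.276), with the muscle phosphoglycerate mutase Pgam2 at 0.82 ± 0.26. Without untreated replicate 1, Pgam2 was at 0.52 and Ndufb5 at 0.34, and the glycolysis median was -0.05. The glycolysis list passed without finerenone replicate 2 (0.0498) and without untreated replicate 3 (median 0.23, 0.0104), but had an adjusted p = 0.868 with an estimated correlation. Fatty acid oxidation had 15 of 25 lower and a median of -0.05 (adjusted p = 0.0987), with Cpt1b, which carries fatty acids into mitochondria, at -0.31 ± 0.11. That list passed after quantile normalization (median -0.17, adjusted p = 0.00261), after cyclic loess (-0.12, 0.00439), with the clock covariate (-0.01, 0.0390), without finerenone replicate 3 (-0.09, 0.0217) and without untreated replicate 1 (-0.09, 0.0396), but not with an estimated correlation (adjusted p = 0.662), and its median was 0.00 without finerenone replicate 2 and 0.01 without untreated replicate 3.

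The lists of excitation and contraction gave medians of -0.05 for calcium handling (adjusted p = 0.302) and -0.07 for potassium and sodium channels and gap junctions (adjusted p = 0.122). Casq1, a calsequestrin, differed by 0.60 ± 0.18 (SE), Kcnj11, a subunit of the ATP-sensitive potassium channel, by -0.40 ± 0.11 and Kcnk3 by -0.53 ± 0.21 (-0.32 without finerenone replicate 2). The calcium list passed without untreated replicate 1 (median -0.11, adjusted p = 0.0340) and the channel list with the clock covariate (-0.11, 0.0390), but with an estimated correlation they had an adjusted p = 0.868 and an adjusted p = 0.662. Vascular tone genes had a median of 0.09 and a mean of 0.02, while the test pointed down (adjusted p = 0.645); Rgs2, a regulator of G protein signalling, differed by -0.67 ± 0.20 and the endothelin receptor Ednrb by -0.47 ± 0.17. Cardiomyocyte markers had a median of 0.00 and a mean of -0.02 with a test that pointed down (adjusted p = 0.644), atrial markers a median of 0.13 (adjusted p = 0.545) and skeletal muscle markers one of -0.11 (adjusted p = 0.302). Within the skeletal list Mybpc2, a myosin-binding protein of fast fibres, was higher by 0.46 ± 0.09 and was the only member to pass adjusted over the list alone (adjusted p = 0.0181), while 0 passed over all genes. Over the 34 lists tested, 2 members passed in this way, with no adjustment for the number of lists.

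Among the remaining cell type lists, fibroblast markers had a median of 0.16 (adjusted p = 0.302) with Mfap5, a microfibril protein, at 0.55 ± 0.14 (SE). Schwann cell and nerve markers had a median of 0.03 (adjusted p = 0.385) with Cdh19 at 0.47 ± 0.12. Endocardium and valve markers had a median of 0.09 (adjusted p = 0.644). Adipocyte genes (median 0.01, mean -0.09, test down, adjusted p = 0.160) and epicardial genes (median 0.01, mean -0.001, test down, adjusted p = 0.798) had medians and tests of opposite sign. The same held for muscle atrophy and growth (median 0.02, mean -0.03, adjusted p = 0.644). Cell cycle genes had a median of 0.08 (adjusted p = 0.318), heat shock and unfolded protein genes one of 0.00 (adjusted p = 0.644) and immediate early genes one of -0.09 (adjusted p = 0.318). Without finerenone replicate 2 the fibroblast (0.0447), epicardial (median -0.28, 0.00947) and cell cycle lists (0.0115) passed, and the immediate early list did so without finerenone replicate 1 (-0.28, 0.0109) or untreated replicate 3 (0.0289). The clock covariate also gave a call to the fibroblast (0.0390) and cell cycle lists (0.00776). With an estimated correlation the epicardial list had an adjusted p = 0.976, the other 3 each had an adjusted p = 0.868, and 0 of the 34 lists passed.

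**Figure D3:**
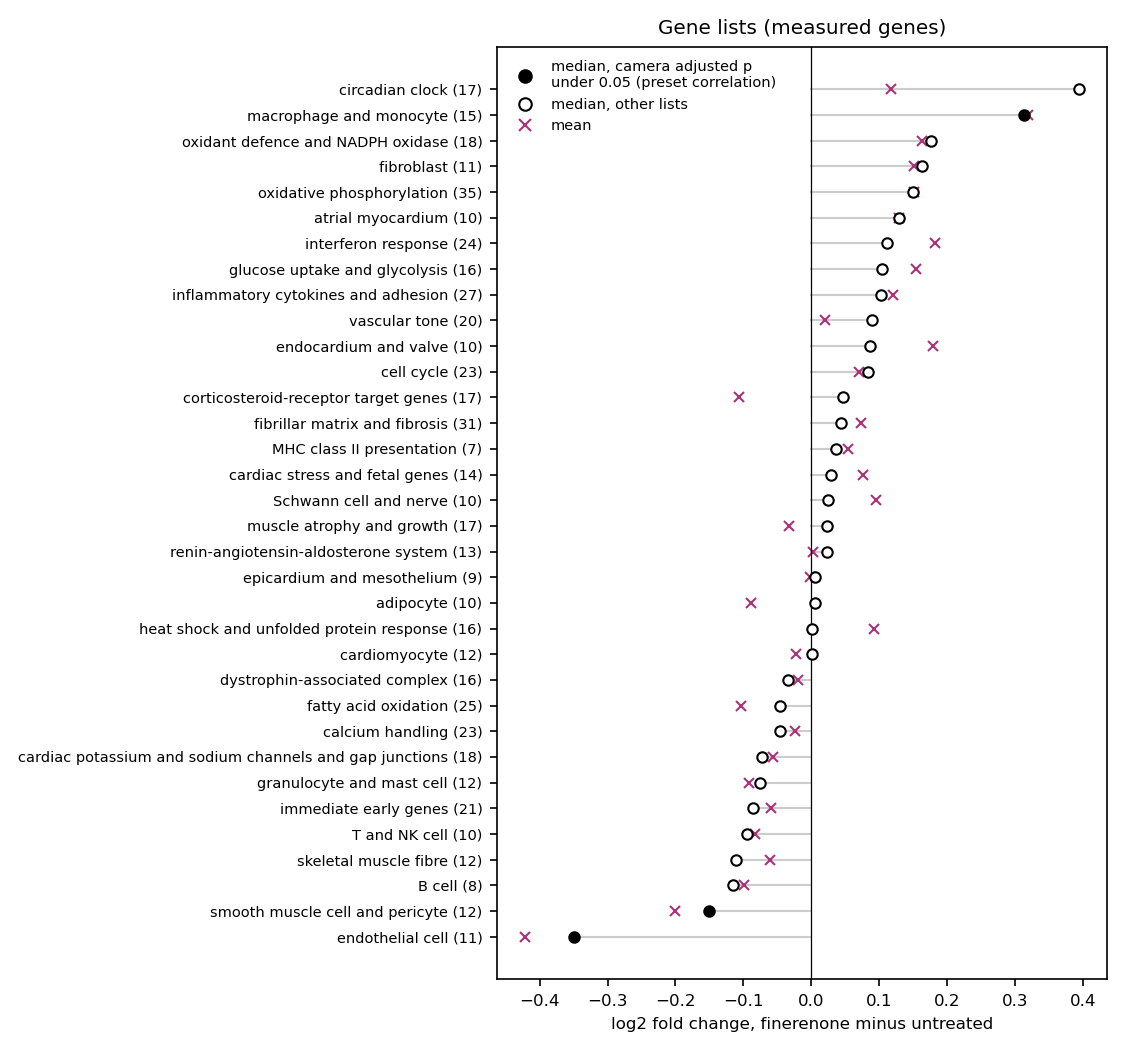
Median (circles) and mean (crosses) log2 fold change, finerenone minus untreated (horizontal axis), of the 34 gene lists, with the number of measured genes in brackets. Filled circles mark the 3 lists with a camera adjusted p below 0.05 at the preset correlation, which had an adjusted p = 0.662 with an estimated correlation.

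Clock genes stood apart in individual treated arrays. The 17 measured genes of the list had a median of 0.40 and a mean of 0.12, while the camera test pointed down (adjusted p = 0.944). The list passed without finerenone replicate 1 (median 0.59, adjusted p = 0.00790) and with the clock score as a covariate (-0.13, 0.00128), a score that 11 of its own genes make up. In the fit of all 6 arrays it had an adjusted p = 0.995 in camera with an estimated correlation. Nr1d1 was the only member to pass adjusted over the list alone (adjusted p = 0.0158), and 0 passed over all genes. Over the 34 lists, 2 members passed in this way, Nr1d1 and Mybpc2, with no adjustment for the number of lists. Dbp, an output factor of the clock, measured 10.99 and 10.79 in finerenone replicates 2 and 3, but 8.06 in finerenone replicate 1 and 8.68 to 9.25 in untreated arrays. The core activator Bmal1, listed under its older symbol Arntl, measured 5.96 and 5.83 in replicates 2 and 3, 8.89 in replicate 1 and 8.27 to 8.90 in untreated arrays. Per2 measured 8.19 and 8.46 against 6.32 in replicate 1 and 6.15 to 6.84 in untreated arrays. Clock differed by -0.86 ± 0.26 (SE).

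**Figure D4:**
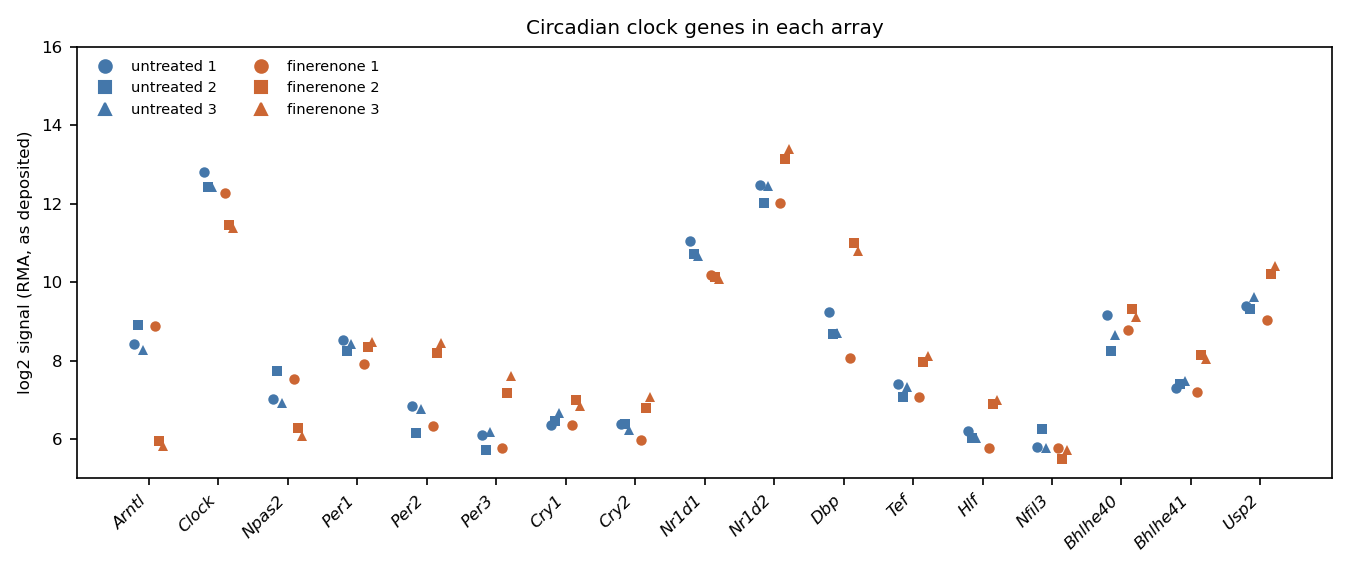
Log2 signal (vertical axis, RMA values as deposited) of the 17 measured genes of the circadian clock list, with 1 point per array. For 15 genes finerenone replicates 2 and 3 lie outside the range of the untreated arrays on one side, and finerenone replicate 1 does so on that side for 2 of them, Clock and Nr1d1.

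Untreated replicate 1 also differed from the other arrays. Alb, the serum albumin made by hepatocytes, measured 16.69 there and 4.10 to 4.38 in the other 5 arrays. On the first principal component (31.2% of the variance) this array lay at -61.6, and the other arrays lay between -12.4 and 39.95. Without it, limma again found 0 genes past the adjusted threshold, and 1932 genes had an unadjusted p below 0.05. Across 11344 genes at a mean of at least 6, the log2 difference between groups and the span of the gene had a Spearman rho of -0.372, and -0.338 without that array, against -0.189 over all 30061 genes with a span, where genes are not independent replicates.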

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

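The clock score as a covariate and the removal of the trend with gene span and signal level were chosen after the data were seen; the other alternatives were fixed beforehand. The count of genes past the adjusted threshold was 0 in limma under every alternative that refitted the genes, with 1685 to 2783 genes at an unadjusted p below 0.05 when single arrays were left out. The planned looser criteria gave 495 genes at a fold of at least 1.5 and 23 at a fold of at least 2, and the filter to a mean of at least 6 left 1306 genes at an unadjusted p below 0.05, from fewer genes tested. With the span and level trend removed, 1836 genes had an unadjusted p below 0.05, and 47.5% of these were higher, against 72.9% of the 2347. The removal centres the differences, so a near-even share was largely built in. The count of lists, 3 at the preset correlation, was 5 after quantile normalization, after cyclic loess, with array weights and on ranks, 13 with the clock covariate, 4 to 13 with single arrays left out, and 0 with fry and with an estimated correlation. At the preset correlation or on ranks, calls were gained by the interferon list (7 alternatives), oxidative phosphorylation (7), fatty acid oxidation (5), B cells (4) and T and NK cells (3). Glycolysis, oxidant defence, cell cycle, immediate early, circadian and fibroblast lists gained 2 each. Corticosteroid targets and ion channels gained a call only with the clock covariate, calcium handling only without untreated replicate 1, and fibrosis, granulocyte and epicardial lists only without finerenone replicate 2. With an estimated correlation the medians stayed at -0.349 (endothelial), -0.15 (smooth muscle) and 0.314 (macrophage) but the calls were lost, as was the macrophage call (0.314) at a mean of at least 6. The smooth muscle median ran from -0.253 to -0.093 with single arrays left out. The cause of these differences was not tested. Same-numbered arrays deviated with correlations of -0.162, 0.165 and 0.146, so the numbers did not pair the samples. With the replicate block 5 lists passed, the interferon and oxidative phosphorylation lists among them, and 0 genes did. Replicates 2 and 3 correlated best with their own number, and replicate 1 did not.

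Of the 109 genes that the naming rule took, 100 kept their sign in all alternatives, and 48 turned or moved by over 1.5 times with some single array left out. Under the clock covariate the value was -0.016 for Nr3c1, -0.311 for Fkbp5, -0.248 for Zbtb16, -0.225 for Lcn2, 0.459 for Nppb and 0.263 for Col3a1. Nr3c1 was -0.029 after quantile normalization and -0.006 after cyclic loess, Fkbp5 -0.042 with array weights, and Col1a1 -0.013 with the span and level trend removed. With single arrays left out, Nr3c1 ran from -0.019 to 0.10, Fkbp5 from -0.14 to 0.361, Per1 from -0.268 to 0.011, Zbtb16 from -0.105 to 0.793, Col1a1 from -0.142 to 0.31, Col3a1 from -0.373 to 0.247 and Krt18 from -0.005 to 0.328.

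Of 34 lists, 20 kept the direction of their test throughout, the 3 that passed among them. The test of the cardiac stress list turned with a median of 0.018 after median centring, 0.029 with the trended prior, the replicate block and ranks, 0.145 with the clock covariate and 0.016 without the span and level trend. That of the MHC class II list turned at 0.033 (quantile), 0.028 (cyclic loess), 0.097 (array weights), 0.209 (clock covariate) and 0.029 (trend removed). That of the circadian list turned at 0.362 (quantile), 0.383 (median centring), 0.379 (cyclic loess), 0.282 (trend removed) and 0.395 (ranks). Others turned for the fibrosis list at a mean of at least 6 (0.048), for immediate early genes with the clock covariate (0.211), and with the trend removed for calcium handling (0.011), heat shock genes (0.007), cardiomyocytes (0.024) and epicardium (-0.049). With single arrays left out, medians of lists whose test turned ran from -0.028 to 0.12 for vascular tone, -0.019 to 0.092 for cardiac stress, -0.009 to 0.141 for fibrosis, 0.02 to 0.156 for cytokines, -0.096 to 0.209 for MHC class II, -0.05 to 0.234 for glycolysis, -0.106 to 0.028 for calcium handling, -0.009 to 0.124 for cell cycle, -0.028 to 0.142 for heat shock genes, -0.278 to -0.003 for immediate early genes, 0.185 to 0.587 for the circadian list, -0.055 to 0.025 for cardiomyocytes, -0.162 to -0.038 for skeletal muscle and -0.283 to 0.254 for epicardium. The cause was not tested. Median centring and the other scalings moved the median over all genes by less than 0.1.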

Other observations

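The tests of the clock pattern were chosen after its values were seen, and the clock score rests on 11 of the 17 measured clock genes, picked after the same look, which limits every test that uses it. The hepatocyte markers, gene span, clock score and spread criteria were also taken up only after the data had been looked at, though the bounds for hepatocyte markers and for the list medians were written before their results.

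Cldn5, the tight junction claudin of endothelium, was singled out after its values were seen because it followed the arrays of the clock genes. It measured 7.35 and 7.40 in finerenone replicates 2 and 3, 9.25 in finerenone replicate 1 and 8.64 to 9.35 in untreated arrays. Cdkn1a followed the same arrays, with 10.24 and 10.27 against 12.13 in finerenone replicate 1.

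The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 3 shifted lists at the preset correlation, and 8 of the 10 splits gave as many, the highest other 12. It gave 2347 genes at an unadjusted p below 0.05, and 2 of the 10 splits gave as many, the highest other 2879. It gave 0 genes past the adjusted threshold in limma, as did all 10 splits.

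Endothelial markers were lower and macrophage markers higher in treated hearts at the preset correlation, but neither list passed with an estimated correlation (adjusted p = 0.662 for each). A trend with gene span and signal level is argued against as the source of either median. Random lists matched on both measures centred on -0.009 (endothelial) and 0.034 (macrophage), and 0% of 10000 had a median as low or as high. Those lists held unrelated genes, while the markers were correlated (estimated at 0.441 and 0.411), so the 0% does not measure chance. With the clock score as a covariate the macrophage median was 0.343 (ratio to 0.314 of 1.09, bootstrap interval over genes 0.733 to 2.27, above the bound of 0.5). For the endothelial list (-0.327) the interval of 0.446 to 2.12 reached below that bound. The score was positive only in finerenone replicates 2 and 3 (1.19 and 1.46), while finerenone replicate 1 (-1.90) lay beside the untreated arrays (-1.90 to -1.13). The covariate fit therefore rests largely on 1 treated array, and the intervals carry no spread between mice. The position of the clock stays undecided for both lists. Without untreated replicate 1, the medians of -0.209 and 0.254 kept over 0.5 of their size, but the intervals of 0.292 to 1.14 and 0.474 to 1.03 reached below it, so that array may carry part of either shift. An effect of finerenone on the share or state of these cells stays open and untested beyond these lists.

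Untreated replicate 1 held transcripts of hepatocytes. Besides Alb at 16.69, Fgb measured 8.96 there against at most 3.83 elsewhere and Apoa2 8.87 against at most 4.01. Of 30 other markers, 22 (73.3%, Wilson interval 55.6 to 85.8) were higher there than in every other array by more than 1 on the log2 scale. A faulty signal of single probe sets, which had to stay under 20%, is argued against by the lower bound of 55.6%. That bound treats markers read on 1 array as independent draws, which they are not, so it measures no spread between samples. All 30 markers were highest in that array, with a lowest excess of 0.33 and a median excess of 1.96 over the highest other array. Liver RNA in that sample is a candidate explanation that goes with these values, but the 73.3% fell short of the 80% set beforehand, so it stays open. Of the 30 markers, 5 were expressed at a mean of at least 6 in the other hearts too. The design gives no biological explanation for a single untreated heart, and none was tested.

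In finerenone replicates 2 and 3, 15 of the 17 measured clock genes lay outside the untreated range on one side, Per1 and Bhlhe40 being the others. Finerenone replicate 1 shared that side for 2 of the 15, Clock and Nr1d1, and lay on the opposite side for 6 and inside the untreated range for 7, so Nr1d1 and Clock were lower in all 3 treated arrays. Finerenone replicate 1 and untreated replicate 2, from different groups, also stood apart together from the other 4 arrays for 10 of the 17 genes. This pair was picked after its values were seen, as the highest besides finerenone replicates 2 and 3. The clock genes are not independent of each other, so the 13.3% of genes expected by chance is no reference for it. Nor is it independent of the 15 genes above, which already place 2 arrays at one end. Clock genes thus varied across arrays within groups too. Since a single array excludes little, an effect of finerenone on the clock in all treated mice stays open beside one in only some. Hearts collected at another time of day could also place 15 genes apart, and this cannot be told apart from the treatment because collection times are not given in the sources used here.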
